A study of Mus musculus with 54 samples.

How the data were processed

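Gene expression was measured by RNA sequencing in 54 libraries from mouse BMDMs of 2 genotypes, untreated or exposed to Pam3 or R837 for 2, 4, 6 or 8 h. Per the labels, marrow was cultured with M-CSF for 5 days, replated and cultured for 2 more days, BMDMs of 3 mice gave the 3 replicates of a group, RNA was purified on columns with DNase, and libraries were made with the TruSeq RNA kit v2 and sequenced on a HiSeq4000 as single-end reads of 50 bp. The strand setting of the counts is not given in the sources used here. The submitters' processing notes name the aligner GSNAP and the genome build GRCm38, and versions and alignment settings are not given in the sources used here. How N4bp1 was deleted and which animals gave which culture are also not given in the sources used here.

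For each library the authors deposited 1 table with, for each of 52636 Ensembl gene identifiers, a whole-number count of reads over exons, not normalized, and an exon width. The deposited RPKM values equal those counts per kilobase of width and per library total, with a total 1.09 to 1.11 times the sum of the counts. Counts were tested and RPKM values were not used here. Gene symbols were taken from the GENCODE annotation release M21 for GRCm38, in which 52403 identifiers had a symbol, and identifiers with no symbol held at most 0.0245% of a library's counts. Locations come from the same annotation, 1-based.

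Groups were formed from the genotype, ligand and time in the labels, with 3 libraries each. Library totals ran from 20.03 to 45.9 M counts. Genes were kept with edgeR's filterByExpr over the 18 groups, with a minimum count of 10 and a minimum total of 15, which left 14970 genes. Without the filter 27757 genes with any count were tested. Scaling used TMM factors, which ran from 0.830 to 1.28. One model with a coefficient per group was fitted to all 54 libraries with edgeR's quasi-likelihood method (glmQLFit and glmQLFTest, robust), so that all groups share 1 estimate of the spread, and Benjamini-Hochberg adjustment was applied within each comparison at 0.05. Knockout was compared with wild type at each of the 9 conditions, each ligand and time with untreated cells in wild type, and R837 with Pam3 at each time in wild type. Interactions between genotype and response were tested with F-tests over the 4 times. The SE of a log2 change was taken as its size divided by the square root of the F statistic. CPM values of single genes use TMM-scaled library sizes, and CPM values of the sample checks (Y-linked genes, Xist, immunoglobulin genes, Nnt) use raw totals. A fold change against a group with 0 counts in all its libraries is given as a lower bound, computed against 3 counts over that group, and such bounds cover counting error only.

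Gene lists were compared with all other genes by limma's camera test with a preset correlation of 0.01, adjusted over the lists and comparisons of a family, for the 26 lists with at least 5 tested genes. They were NF-kB feedback inhibitors and subunits, cytokines, chemokines, immediate-early genes, interferon-stimulated genes, the IkB kinase family and adaptors, caspase-8 and cell death, Toll-like receptors and adaptors, N4BP1-related and CCCH endonucleases, inflammatory effector enzymes and glycolysis, cholesterol biosynthesis, LXR targets, MHC class II and co-stimulation, cell cycle, the unfolded protein and integrated stress response, NRF2 targets, homeostatic macrophage genes, and markers of core macrophages, neutrophils, monocytes, dendritic cells, B cells, mast cells and basophils, stromal and endothelial cells, megakaryocytes and osteoclasts. Lists for T and NK cells and for erythroid cells had 4 and 2 tested genes and were not tested. Of the 234 list tests between genotypes 103 passed with the preset correlation and 30 with an estimated one, and of the 208 in wild-type responses 105 and 65 passed. R837 against Pam3 was compared by list only through counts of genes.

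Genes are named by a rule. It takes N4bp1 in every library, the 10 largest increases and decreases between genotypes in untreated cells and at 8 h of each ligand and the 5 largest at the other times, the 10 largest at 2 and 8 h and the 5 largest at 4 and 6 h for each wild-type response, the 5 largest for R837 against Pam3, and the 10 smallest F-test p-values for interactions. Such genes had to pass the test, reach a mean of 5 CPM in the higher group and have all 3 libraries of one group above all 3 of the other, and gene models with a placeholder symbol were skipped. The rule adds 19 cytokine, chemokine and signalling genes chosen in advance and, for each list described, up to 4 members with the smallest p-value. Fewer genes than the rule gives are named, from the top of each part. Igha, Xist and Nnt were named as properties of libraries, after their values were seen.

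Replicates were compared before they were averaged. The chi-square statistic per degree of freedom between libraries of a group, over genes with at least 20 counts, ran from 6.62 to 89.8 over 54 pairs, so no pair differed by as little as sampling noise. The labels give the same replicate numbers to all groups, and whether equal numbers pair libraries was read from the correlation of their deviations from the group means. It was over 0.1 for all 3 numbers in the wild-type R837 responses, where it ran from 0.219 to 0.632, and in R837 against Pam3 at 2 h, where it ran from 0.101 to 0.662. At 2 h, however, replicates 1 and 2 of the ligands had Y-linked levels in opposite order, so equal numbers were taken as pairs in the R837 responses alone. The correlation was not over 0.1 for all 3 numbers in any other comparison.

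Alternatives were RLE size factors in place of TMM, no filter on low counts, a stricter filter of at least 1 CPM in at least 3 libraries, DESeq2, the replicate number as a block, limma voom with the replicate number as a random effect (consensus correlation 0.0424), a fit of only the groups compared, each library left out in turn, and for lists an estimated correlation in camera and limma's fry. A further 3 alternatives were chosen after seeing the data. They leave out KO Pam3 8 h replicate 3, add the Y-linked level as a covariate, and block wild-type libraries by Y-linked level. The order of Y-linked levels over the replicate numbers differed between untreated and Pam3 libraries of wild type. The block and the random effect by number therefore do not follow cultures there, and the correlation of 0.0424 need not be that of libraries of 1 culture. The computations used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. The steps were tested on simulated data, drawn for 14970 genes from the means and sizes of the libraries with known changes between KO and WT at R837 6 h. There edgeR recovered 83% of genes changed 2-fold and 99% of genes changed 4-fold with 3.92% false calls. DESeq2 recovered 86% and limma voom 83% of 2-fold genes, and the interaction F-test recovered 92% of 4-fold genes. The simulated libraries were drawn independently, with 1 spread per gene for all groups, no culture shared between conditions and no library of low complexity. The real groups differed in spread, so these rates check the steps and need not hold for the data.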

Results

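RNA sequencing measured gene expression in bone marrow-derived macrophages (BMDMs), which grow from mouse bone marrow cells under the growth factor M-CSF. Cells came from wild-type mice or from mice lacking N4bp1, which encodes an RNA-binding protein that restrains NF-kB signalling and is cleaved by caspase-8. They were left untreated or were exposed for 2, 4, 6 or 8 h to either of 2 ligands of Toll-like receptors. Pam3CSK4 (Pam3) is a synthetic lipopeptide that activates TLR2 together with TLR1, and R837 (imiquimod) is a small molecule that activates TLR7. The 2 genotypes and 9 conditions gave 18 groups of 3 libraries, 54 in all, and per the labels each replicate was a culture from a separate mouse. Library totals ran from 20.03 to 45.9 M counts with a median of 29.9 M. After a filter on low counts 14970 genes were tested. Expression levels below are read counts scaled to library size (CPM), as mean ± SD of n = 3 libraries per group. Changes are log2 ratios ± SE, tested with edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named. The series title places the study on an axis between N4BP1 and caspase-8. The comparisons below ask how each ligand changed expression in wild-type cells and how knockout (KO) cells differed from wild-type (WT) cells at each time.

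N4bp1 itself (ENSMUSG00000031652, chromosome 8, 86808160 to 86885258, minus strand, GRCm38) was lower in every KO library than in every WT library of the same condition. In untreated cells it stood at 36.2 ± 5.28 CPM in KO and 64.7 ± 1.02 CPM in WT libraries (SD, n = 3 each), a log2 difference of -0.84 ± 0.10 (edgeR adjusted p = 5.12e-07). The most negative of the 9 log2 differences was at R837 4 h, with 180.5 ± 23.4 CPM in KO and 585 ± 21.7 CPM in WT libraries, a log2 difference of -1.70 ± 0.10 (edgeR adjusted p = 1.56e-16). At the remaining conditions the log2 differences were -1.41 ± 0.10, -0.93 ± 0.10, -1.04 ± 0.10 and -0.78 ± 0.10 after 2, 4, 6 and 8 h of Pam3, and -1.48 ± 0.10, -1.46 ± 0.10 and -1.18 ± 0.10 after 2, 6 and 8 h of R837. KO libraries still held 1101 to 7820 counts of N4bp1, against 2106 to 19579 in WT libraries. Which part of the gene was deleted is not given in the labels. Counts from the whole gene therefore do not separate a lower transcript level from reads lost with a deleted part. They also do not show whether protein was made.

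Several properties of the libraries moved with genotype or set single libraries apart. All 27 KO libraries had at most 0.208 CPM of Y-linked transcripts. Among WT libraries each condition held 1 with 162.4 to 206.7 CPM of Y-linked transcripts, 1 with 57.3 to 77.7 CPM and 1 with at most 0.160 CPM. Xist, the transcript of the inactive X chromosome, was at 61.8 to 238.5 CPM in KO libraries, and at 17 to 26.8, 80.8 to 134.0 and 88.0 to 140.6 CPM in WT libraries with high, middle and no Y-linked counts. The 9 libraries with middle Y-linked counts thus held both Y-linked transcripts and Xist, which cells of 1 male or 1 female mouse would not. The 9 libraries with high Y-linked counts also held both, with Xist at the lower level of 17 to 26.8 CPM. These values go against 1 mouse per culture for the middle libraries and put it in doubt for the high ones. For that reason n = 3 below counts libraries and not mice. Transcripts of plasma cells also differed. Igha, the heavy chain of immunoglobulin A, was at 23.6 to 91.2 CPM in KO libraries, against 0.333 to 1.61, 2.15 to 4.90 and 9.36 to 15.1 CPM in those WT libraries in the same order. Jchain, which joins secreted antibodies, was at 7.98 to 19.4 CPM in KO libraries and 0.0796 to 4.34 CPM in WT libraries. KO Pam3 8 h replicate 3 had counts in 12263 genes, against 16097 to 18039 in the other 53 libraries, and in 12098 genes against at least 15684 once every library was thinned to 20033154 counts. The next lowest, with 16097 and 15684 genes, was KO Pam3 6 h replicate 3. Mitochondrially encoded genes took 0.0769 to 0.243% of counts across the 54 libraries. Nnt, which carries a deletion in C57BL/6J mice, was at most 0.736 CPM in any library, while the labels give the wild-type animals as C57BL/6N.

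In wild-type cells Pam3 raised cytokine genes within 2 h. The endothelial adhesion molecule gene Sele rose at least 278-fold from 0 counts in untreated libraries, and the cytokine subunit gene Il23a rose at least 210-fold. Socs3, a feedback inhibitor of cytokine receptors, rose from 1.21 ± 0.340 to 2217 ± 54.4 CPM, a log2 change of 10.85 ± 0.15 (edgeR adjusted p = 3.87e-43). The neutrophil chemokine gene Cxcl1 reached 323 ± 95 CPM and Il1b 1105 ± 95.3 CPM. The largest falls at 2 h were in the lysophosphatidic acid receptor gene Lpar6 (3.18 ± 1.05 against 58.6 ± 3.03 CPM, log2 -4.20 ± 0.26, edgeR adjusted p = 2.53e-18), in Frat1 (log2 -4.08 ± 0.60) and in Hhex (log2 -3.74 ± 0.27). By 8 h Il6 stood at least 1550-fold above untreated cells, and Csf3, which encodes the granulocyte growth factor G-CSF, at least 667-fold above. Angptl4, an inhibitor of lipoprotein lipase, fell from 32.1 ± 9.37 to 0.232 ± 0.173 CPM (log2 -7.03 ± 0.53, edgeR adjusted p = 2.6e-15). Tnf changed by log2 6.73 ± 0.28, 7.09 ± 0.28, 7.71 ± 0.29 and 7.42 ± 0.28 at 2, 4, 6 and 8 h. N4bp1 rose by log2 2.08 ± 0.10, 1.87 ± 0.10, 2.15 ± 0.10 and 2.16 ± 0.10 at those times. Of the 14970 genes, 3308 rose and 2829 fell at 2 h, 3784 and 3548 at 4 h, 4019 and 3992 at 6 h, and 3938 and 3871 at 8 h. With RLE size factors the balance turned at 4, 6 and 8 h (3623 and 3717, 3864 and 4143, 3756 and 4068).

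The gene lists described below were fixed before the data were examined, and each was also compared with all other genes by limma's camera test with Benjamini-Hochberg adjustment. A count adjusted over the list alone is given where it differs from that over all genes tested, and an estimated correlation where it ended a list's call. Of the 20 NF-kB feedback inhibitors and subunits, 19 rose and 1 did not pass after 2 h of Pam3 (camera adjusted p = 1.21e-105). Nfkbia, which encodes the inhibitor IkB-alpha, had a log2 change of 5.18 ± 0.09 (edgeR adjusted p = 1.42e-38), and Nfkbie 5.61 ± 0.13. Of 21 cytokine genes 21 rose at 2 h (camera adjusted p = 1.22e-26). Of 22 chemokine genes 22 rose at 8 h (camera adjusted p = 1.99e-28). Among 30 interferon-stimulated genes 26 rose and 4 did not pass at 2 h and 30 rose at 8 h. The interferon-stimulated list had camera adjusted p = 2.39e-05, and adjusted p = 0.456 with an estimated correlation at 2 h, and adjusted p = 2.1e-17, and adjusted p = 0.0851 with an estimated correlation at 8 h. Of 24 genes of caspase-8 signalling and cell death 19 rose, 2 fell and 3 did not pass at 2 h (camera adjusted p = 3.51e-12), among them the inflammasome sensor gene Nlrp3 (log2 5.08 ± 0.17). Casp8 itself had a log2 change of 0.18 ± 0.13 (edgeR adjusted p = 0.272) at 2 h. At 8 h it was 0.41 ± 0.13 (edgeR adjusted p = 0.00577, and from 0.00178 to 0.0913 over the alternatives, the highest without WT Pam3 8 h replicate 2). Of 17 genes of IkB kinases and their adaptors 12 rose, 4 fell and 1 did not pass at 2 h (camera adjusted p = 1.71e-05). Ikbke, the inducible kinase of that family, changed by log2 1.70 ± 0.11 at 2 h and 3.01 ± 0.12 at 8 h, and Tbk1 by 0.37 ± 0.08 and 0.98 ± 0.08. All 20 effector enzyme and glycolysis genes rose at 8 h (camera adjusted p = 9.56e-28), among them Sod2 (log2 4.96 ± 0.09) and the prostaglandin synthase gene Ptges (log2 8.45 ± 0.19).

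R837 raised cytokine genes together with interferon-stimulated genes in wild-type cells. Nos2, the inducible nitric oxide synthase gene, reached 99.3 ± 24.5 CPM at 2 h and 1681 ± 189 CPM at 6 h. The chemokine gene Cxcl11 rose at least 277-fold at 2 h and Il6 rose at least 3600-fold at 4 h, in both cases from 0 counts in untreated cells. At 8 h Csf3 stood at least 2220-fold above untreated cells and Il6 at least 2000-fold. The largest fall at 8 h was in Sox4, a transcription factor gene of progenitor cells (0.277 ± 0.206 against 58.1 ± 5.91 CPM, log2 -7.60 ± 0.47, edgeR adjusted p = 2.73e-18), followed by Angptl4 (log2 -7.19 ± 0.55). Tnf changed by log2 6.84 ± 0.28, 8.41 ± 0.30, 8.33 ± 0.30 and 7.98 ± 0.29 at 2, 4, 6 and 8 h. N4bp1 changed by 2.76 ± 0.11, 3.18 ± 0.11, 3.05 ± 0.11 and 2.78 ± 0.11. Casp8 rose by log2 0.55 ± 0.13 at 2 h (edgeR adjusted p = 0.000416), 1.69 ± 0.13 at 4 h, 1.70 ± 0.13 at 6 h and 1.15 ± 0.13 at 8 h. In all, 3329 genes rose and 2956 fell at 2 h, 3953 and 4098 at 4 h, 4320 and 4541 at 6 h, and 4234 and 4351 at 8 h. With the stricter filter the balance turned at 4 h (3953 and 3903). All 30 interferon-stimulated genes rose at each of the 4 times, with camera adjusted p = 8.34e-29 at 4 h. Isg15, which encodes a ubiquitin-like protein, was among them at 4 h with 1075 ± 83.2 against 17.99 ± 0.209 CPM (log2 5.90 ± 0.26, edgeR adjusted p = 1.64e-22). Of the 20 NF-kB genes 20 rose at 2 h (camera adjusted p = 2.12e-100). Of the 21 cytokine genes 21 rose at 4 h (camera adjusted p = 1.41e-20). Of the 24 cell death genes 20 rose, 2 fell and 2 did not pass at 4 h (camera adjusted p = 5.88e-16). Of the 17 IkB kinase genes 13 rose and 4 fell at 4 h (camera adjusted p = 1.7e-06). Ikbke stood at log2 3.25 ± 0.12 and Tbk1 at 1.09 ± 0.08.

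A direct test of R837 against Pam3 in wild-type cells found interferon-stimulated genes higher under R837. At 2 h Mx2, an antiviral GTPase gene, was at 77.6 ± 15.4 against 5.17 ± 0.602 CPM under R837 and Pam3 (log2 3.91 ± 0.34, edgeR adjusted p = 4.63e-10), and Ifit1 followed (log2 3.20 ± 0.32). At 4 h Tnfsf10, the gene of the death receptor ligand TRAIL, was at 207 ± 16.9 against 2.87 ± 0.614 CPM (log2 6.17 ± 0.48, edgeR adjusted p = 2.28e-13). Ifit3b (log2 5.88 ± 0.40) and the antiviral gene Rsad2 (7548 ± 523 against 129 ± 15.9 CPM, log2 5.87 ± 0.45) followed. At 6 and 8 h the largest difference was in the endothelial lipase gene Lipg, with log2 5.17 ± 0.47 and 4.20 ± 0.45. On the other side, Gdf15 was lower under R837 at 2 h (log2 -2.93 ± 0.49, edgeR adjusted p = 0.000102). Its adjusted p ran from 6.13e-55 to 0.0878 over the alternatives, the highest in a fit of the 6 libraries alone. Sphk1 at 4 h (log2 -2.69 ± 0.34) and the neutrophil chemokine gene Cxcl3 at 6 h (65.6 ± 19.8 against 282 ± 35.1 CPM, log2 -2.10 ± 0.18) and 8 h (log2 -1.79 ± 0.18) were lower as well. Of 30 interferon-stimulated genes, 17 rose, 30 rose, 29 rose and 16 rose under R837 relative to Pam3 at 2, 4, 6 and 8 h. Of the 21 cytokine genes 14 rose and 7 did not pass (15 rose adjusted over the list alone) at 4 h. Of the 24 cell death genes 15 rose, 1 fell and 8 did not pass at 6 h. The anti-inflammatory cytokine gene Il10 was higher under R837 by log2 3.27 ± 0.19 at 6 h and 2.69 ± 0.19 at 8 h. Casp8 was higher by 1.65 ± 0.13 at 4 h (edgeR adjusted p = 4.11e-14). N4bp1 was higher by 0.68 ± 0.10, 1.31 ± 0.10, 0.90 ± 0.10 and 0.62 ± 0.10 at the 4 times. In total 383 genes were higher and 332 lower under R837 at 2 h, 1558 and 1717 at 4 h, 1829 and 1567 at 6 h, and 1072 and 654 at 8 h. At 2 h the balance turned with limma voom (424 and 444). At 4 h it turned with RLE size factors (1700 and 1521), the stricter filter (1765 and 1571) and DESeq2 (1833 and 1659), among others. The 715 calls at 2 h became 418 and 423 without Pam3 replicates 1 and 3 and 353 without R837 replicate 1. The 1726 at 8 h became 1126 without Pam3 replicate 3 and 975 without R837 replicate 3.

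Before any ligand was added, KO macrophages had higher levels of Saa3, of complement C3 and of 4 NF-kB feedback genes than WT macrophages. Saa3, an acute-phase protein gene of macrophages, was at 122 ± 43.4 against 11.8 ± 7.91 CPM in KO and WT cells (log2 3.37 ± 0.28, edgeR adjusted p = 1.67e-10). Slc39a4, a zinc importer gene, was at 9.37 ± 1.97 against 2.34 ± 0.283 CPM (log2 2.00 ± 0.21, edgeR adjusted p = 2.82e-08), and Mefv, which encodes the inflammasome protein pyrin, was higher by log2 1.74 ± 0.34. Complement C3 was at 156 ± 24.8 against 56.96 ± 9.88 CPM (log2 1.45 ± 0.21). Of the 20 NF-kB feedback genes 4 rose and 16 did not pass (8 rose and 1 fell adjusted over the list alone) (camera adjusted p = 5.9e-07, and adjusted p = 0.113 with an estimated correlation). They were Nfkbie at log2 0.76 ± 0.11, Traf1 at 1.05 ± 0.16, Tnip3 at 0.89 ± 0.14 and Nfkbia at 0.41 ± 0.08. Of the 17 IkB kinase genes 2 rose and 15 did not pass (camera adjusted p = 0.175). Among them was Map3k14, the kinase of the non-canonical NF-kB pathway (70.7 ± 5.37 against 31.04 ± 1.22 CPM, log2 1.19 ± 0.13, edgeR adjusted p = 2.82e-08). The fractalkine receptor gene Cx3cr1 was higher by log2 1.29 ± 0.19. The growth arrest gene Gas6 and the mannose receptor gene Mrc1 were lower by log2 -0.64 ± 0.12 and -0.54 ± 0.12. Of 10 stromal and endothelial markers 2 fell and 8 did not pass (3 fell adjusted over the list alone) (camera adjusted p = 3.13e-05). Among them was the collagen gene Col1a2 (5.83 ± 0.369 against 13.03 ± 2.86 CPM, log2 -1.16 ± 0.20). By size the first of the increases was in Jchain (8.06 ± 1.27 against 0.670 ± 0.495 CPM, log2 3.55 ± 0.82, edgeR adjusted p = 0.0207). It no longer passed without WT replicate 1 or 2 or KO replicate 2 or 3 (adjusted p = 0.162, 0.134, 0.0641 and 0.0556). Without WT replicate 1 neither Gas6 nor Mrc1 passed (edgeR adjusted p = 0.0666 and 0.0629). Mrc1 had adjusted p = 0.0824 without KO replicate 2, and Nfkbia had adjusted p = 0.0667 without WT replicate 2. Over the alternatives the adjusted p of Nfkbia ran from 0.000185 to 0.111 and that of Traf1 from 2.5e-13 to 0.0522, both highest in a fit of the 6 libraries alone. That of Mefv ran from 1.41e-31 to 0.144, highest with limma voom, that of Jchain from 1.04e-37 to 0.162, that of Gas6 from 8.41e-07 to 0.0666 and that of Mrc1 from 5.18e-05 to 0.0824. Altogether 77 genes were higher and 55 lower in KO cells. The balance turned with limma voom, to 78 higher and 113 lower, and was 31 and 9 without WT replicate 1. That count of 132 became 40, 71 and 83 without WT replicates 1, 2 and 3, and 85 and 70 without KO replicates 1 and 2.

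Under Pam3, KO cells carried more transcript of the chemokine gene Cxcl3 and of the cytokine genes Il6, Il12b and Tnf than WT cells. Cxcl3 (chromosome 5, 90786103 to 90789600, GRCm38) was at 625 ± 128 against 97.3 ± 13.9 CPM at 4 h, 1711 ± 154 against 282 ± 35.1 CPM at 6 h and 1783 ± 164 against 179.7 ± 24.7 CPM at 8 h in KO and WT cells. Its log2 difference at 8 h was 3.31 ± 0.19 (edgeR adjusted p = 2.3e-16). Il6 (chromosome 5, 30013114 to 30019981) was at 148 ± 33.5 against 21.02 ± 0.634 CPM at 4 h and 373 ± 123 against 44.9 ± 11 CPM at 8 h. The log2 differences were 2.82 ± 0.30 and 3.06 ± 0.30 (edgeR adjusted p = 7.81e-08 and 1.33e-09). Il12b (chromosome 11, 44400063 to 44414033), the shared subunit of interleukin-12 and interleukin-23, was at 111 ± 72 against 14.2 ± 3.78 CPM at 8 h (log2 2.98 ± 0.41, edgeR adjusted p = 7.88e-07). Tnf (chromosome 17, 35199381 to 35202007) was at 3089 ± 410.0 against 1421 ± 206 CPM at 8 h (log2 1.12 ± 0.21, edgeR adjusted p = 0.000146). At 8 h the largest increases were in the glutamate transporter gene Slc1a2 (9.24 ± 5.74 against 0.348 ± 0.160 CPM, log2 4.74 ± 0.61), in the non-coding gene U90926 (log2 3.40 ± 0.39), in Ptx3, which encodes the secreted pattern receptor pentraxin (log2 3.32 ± 0.53), and in Cxcl3. The largest decreases at 8 h were in the ubiquitin ligase gene Rnf144b (log2 -3.13 ± 0.41) and in Hip1 (3.98 ± 0.294 against 22.2 ± 4.34 CPM, log2 -2.48 ± 0.22, edgeR adjusted p = 3.47e-11). Next came falls in Nxpe5 (log2 -2.46 ± 0.36) and Mtss1 (16.5 ± 4.97 against 81.6 ± 3.27 CPM, log2 -2.31 ± 0.23). At 2 h the complement regulator gene Cd55 was at 9.70 ± 2.01 against 1.94 ± 0.975 CPM (log2 2.32 ± 0.37, edgeR adjusted p = 0.000264). Genes higher and lower in KO cells numbered 98 and 116 at 2 h, 499 and 463 at 4 h, 584 and 612 at 6 h, and 1714 and 1863 at 8 h. The balance turned with RLE size factors at 4 h (466 and 500), the stricter filter at 6 h (652 and 638) and without KO replicate 3 at 8 h (1345 and 1335), among others.

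The counts under Pam3 depended on single libraries and on which libraries entered the fit. The 214 calls at 2 h became 116, 95 and 142 without WT replicates 1, 2 and 3, and 80 and 63 without KO replicates 2 and 3. The 962 calls at 4 h became 535 and 520 without WT replicates 2 and 3, and 409 and 547 without KO replicates 1 and 2. The 1196 calls at 6 h became 696 and 716 without WT replicates 2 and 3 and 635 without KO replicate 3. Fitted on the 6 libraries of the comparison alone, 330 genes passed at 2 h, 506 at 6 h and 451 at 8 h, in place of 214, 1196 and 3577. At 8 h 2680 genes passed without KO replicate 3, the library with counts in 12263 genes. Over the alternatives the adjusted p at 8 h ran from 6.11e-39 to 0.162 for Rnf144b and from 3.78e-33 to 0.259 for Nxpe5, both highest in that fit of 6 libraries.

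By list, 7 rose of the 21 cytokine genes at 4 h under Pam3, 11 at 6 h and 15 at 8 h in KO relative to WT cells (11, 15 and 15 adjusted over the list alone). Il12a (log2 3.14 ± 0.39) and Il1a (log2 2.45 ± 0.31) were among those at 8 h beside Il6. The cytokine list had camera adjusted p = 3.85e-09 at 4 h, adjusted p = 8.28e-12 at 6 h and adjusted p = 5.6e-11 at 8 h. Among 22 chemokine genes 8 rose and 14 did not pass at 4 h, 8 rose, 2 fell and 12 did not pass (9 rose and 3 fell adjusted over the list alone) at 6 h and 8 rose, 5 fell and 9 did not pass at 8 h. Cxcl1 stood at log2 2.14 ± 0.25, Ccl3 at 0.98 ± 0.12 and Cxcl2 at 1.80 ± 0.23 at 8 h. Their list had camera adjusted p = 2.84e-09 at 4 h, adjusted p = 3.34e-05, and adjusted p = 0.143 with an estimated correlation at 6 h and adjusted p = 0.00025, and adjusted p = 0.187 with an estimated correlation at 8 h. Of the 20 NF-kB feedback genes 7 rose and 13 did not pass (10 rose adjusted over the list alone) at 4 h, 10 rose and 10 did not pass (14 rose adjusted over the list alone) at 6 h and 9 rose and 11 did not pass (11 rose and 1 fell adjusted over the list alone) at 8 h. Traf1 stood at log2 1.28 ± 0.14 and Tnfaip3, which encodes the deubiquitinase A20, at 1.15 ± 0.13 at 8 h. The NF-kB list had camera adjusted p = 6.6e-07, and adjusted p = 0.114 with an estimated correlation at 4 h, adjusted p = 4.24e-11 at 6 h and adjusted p = 3.86e-06, and adjusted p = 0.143 with an estimated correlation at 8 h. Interferon-stimulated genes went the other way at 8 h, where 12 fell and 18 did not pass (13 fell adjusted over the list alone) of 30 (camera adjusted p = 0.00371, and adjusted p = 0.685 with an estimated correlation). Ifit3 (log2 -1.38 ± 0.29) and Ifit2 (log2 -1.68 ± 0.36) were among them. Without KO replicate 3, 16 cytokine genes rose at 8 h, 8 chemokine genes rose and 2 fell, 8 NF-kB genes rose and 8 interferon-stimulated genes fell. The 24 cell death genes had camera adjusted p = 0.48 at 8 h, where 4 rose, 1 fell and 19 did not pass. The inhibitor of apoptosis gene Birc2 stood at log2 0.69 ± 0.15 and Bcl2l1 at -0.60 ± 0.14. Of the 17 IkB kinase genes 4 rose, 3 fell and 10 did not pass at 8 h (camera adjusted p = 0.372). Ikbkb stood at log2 0.53 ± 0.11 and Tank at 0.50 ± 0.11. Over the alternatives the adjusted p at 8 h ran from 8.02e-54 to 0.0513 for Ifit2, from 2.4e-06 to 0.136 for Bcl2l1 and from 2.66e-05 to 0.0811 for Ikbkb, each highest in a fit of the 6 libraries alone.

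Under R837, KO cells had less transcript of the interferon-stimulated genes Rsad2 and Cmpk2 than WT cells at 4 and 6 h, and more of Il12b, Il6 and Cxcl3 at 6 and 8 h. Rsad2 (chromosome 12, 26442746 to 26456452, GRCm38) was at 1577 ± 711 against 7548 ± 523 CPM at 4 h and 428 ± 38.7 against 3217 ± 449 CPM at 6 h in KO and WT cells (log2 -2.26 ± 0.38 and -2.91 ± 0.39, edgeR adjusted p = 4.22e-05 and 4.7e-07). Cmpk2, a nucleotide kinase gene beside it (chromosome 12, 26469204 to 26479837), was lower by log2 -2.24 ± 0.33 and -2.87 ± 0.34 at those times. Il12b was at 1086 ± 387 against 174 ± 73.9 CPM at 6 h and 947 ± 264 against 73.8 ± 36.6 CPM at 8 h (log2 2.64 ± 0.39 and 3.68 ± 0.41, edgeR adjusted p = 2.69e-06 and 1.69e-08). Cxcl3 was at 65.3 ± 5.63 against 23.4 ± 3.98 CPM, 342 ± 15.4 against 48.98 ± 8.52 CPM, 593 ± 96.1 against 65.6 ± 19.8 CPM and 324 ± 35.4 against 51.99 ± 3.65 CPM at 2, 4, 6 and 8 h. Il6 was higher by log2 1.86 ± 0.28 at 6 h and 2.86 ± 0.30 at 8 h. Casp8 (chromosome 1, 58795374 to 58847503) was lower in KO cells, with 97.98 ± 20.2 against 186 ± 13.9 CPM at 4 h and 95.1 ± 1.38 against 186 ± 13.9 CPM at 6 h (log2 -0.92 ± 0.13 and -0.97 ± 0.13, edgeR adjusted p = 6.21e-07 and 1.18e-07). At 4 h the largest decreases were in the interferon-induced gene Ifit1bl1 (29.02 ± 13.2 against 256 ± 39.2 CPM, log2 -3.14 ± 0.35), in Ndnf (log2 -2.64 ± 0.34) and in Tnfsf10 (35.5 ± 12.5 against 207 ± 16.9 CPM, log2 -2.55 ± 0.39). At 8 h the largest increases were in Il12b and Ptx3 (log2 3.19 ± 0.52), and the largest decreases in Ifit1bl1 (log2 -2.72 ± 0.35) and in the transcription factor gene Nfatc2 (log2 -2.53 ± 0.44). Genes higher and lower in KO cells numbered 220 and 182 at 2 h, 581 and 983 at 4 h, 1012 and 1452 at 6 h, and 1074 and 1308 at 8 h. At 2 h the balance turned with RLE size factors (193 and 199), DESeq2 (275 and 335), limma voom (263 and 305), no filter on low counts (315 and 321) and the compared groups alone (341 and 372). The 402 calls at 2 h became 197, 247 and 229 without WT replicates 1, 2 and 3, 213, 215 and 266 without KO replicates 1, 2 and 3, and 713 in a fit of those 6 libraries alone. The 1564 calls at 4 h became 932 without KO replicate 2.

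Of the 30 interferon-stimulated genes, 22 fell and 8 did not pass (28 fell adjusted over the list alone) at 4 h of R837 in KO relative to WT cells, 26 fell and 4 did not pass (28 fell adjusted over the list alone) at 6 h and 19 fell and 11 did not pass (25 fell adjusted over the list alone) at 8 h. The list's median log2 difference was -0.88 at 4 h and -1.08 at 6 h. It had camera adjusted p = 9.49e-20, and adjusted p = 0.0941 with an estimated correlation at 4 h. The values were adjusted p = 7.87e-20, and adjusted p = 0.0941 with an estimated correlation at 6 h and adjusted p = 5.14e-10, and adjusted p = 0.293 with an estimated correlation at 8 h. Ifi204, an interferon-inducible DNA sensor gene, was lower by log2 -0.98 ± 0.19 at 4 h, and Ifit2 by -2.59 ± 0.37 at 6 h and -2.09 ± 0.36 at 8 h. Of the 24 cell death genes 1 rose, 8 fell and 15 did not pass (3 rose and 9 fell adjusted over the list alone) at 4 h (camera adjusted p = 0.00994, and adjusted p = 0.323 with an estimated correlation). At 6 h 3 rose, 10 fell and 11 did not pass (3 rose and 11 fell adjusted over the list alone) (camera adjusted p = 4e-05, and adjusted p = 0.0941 with an estimated correlation). Beside Casp8, the survival gene Bcl2l1 (59.4 ± 1.46 against 174 ± 30.1 CPM, log2 -1.55 ± 0.14) and the necroptosis effector gene Mlkl (log2 -1.26 ± 0.15) fell at 6 h. At 8 h 4 rose, 7 fell and 13 did not pass (5 rose and 9 fell adjusted over the list alone) (camera adjusted p = 0.329), with Birc2 at log2 0.95 ± 0.15. Chemokine genes moved both ways at 6 h, where 5 rose, 8 fell and 9 did not pass (5 rose and 9 fell adjusted over the list alone) of 22 (camera adjusted p = 0.81). The monocyte chemokine genes Ccl7 and Ccl12 stood at log2 -2.21 ± 0.25 and -1.90 ± 0.23. Cxcl10, a chemokine induced by interferon, was at 256 ± 5.46 against 1498 ± 429 CPM at 6 h (log2 -2.55 ± 0.43, edgeR adjusted p = 3e-05). Of the 21 cytokine genes 4 rose, 2 fell and 15 did not pass at 4 h (camera adjusted p = 0.26). At 6 h 6 rose, 1 fell and 14 did not pass (7 rose and 1 fell adjusted over the list alone) (camera adjusted p = 0.00685, and adjusted p = 0.43 with an estimated correlation). By 8 h 14 rose and 7 did not pass (camera adjusted p = 5.81e-11). Il10 was lower by log2 -0.79 ± 0.18 at 4 h and higher by 0.88 ± 0.18 at 8 h (edgeR adjusted p = 0.00165 and 0.000292). Over the alternatives its adjusted p at 4 h ran from 1.32e-10 to 0.0883, highest in a fit of the 6 libraries alone. Of the 20 NF-kB genes 9 rose, 1 fell and 10 did not pass (11 rose and 1 fell adjusted over the list alone) at 8 h (camera adjusted p = 3.86e-06, and adjusted p = 0.143 with an estimated correlation). Traf1 stood at log2 1.10 ± 0.14 and Tnfaip3 at 0.94 ± 0.13. The 17 IkB kinase genes had camera adjusted p from 0.175 to 0.955 over the 9 comparisons. At R837 6 h 3 rose, 3 fell and 11 did not pass (4 rose and 3 fell adjusted over the list alone), with Azi2, an adaptor of TBK1, at log2 -0.70 ± 0.11.

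**Figure D1:**
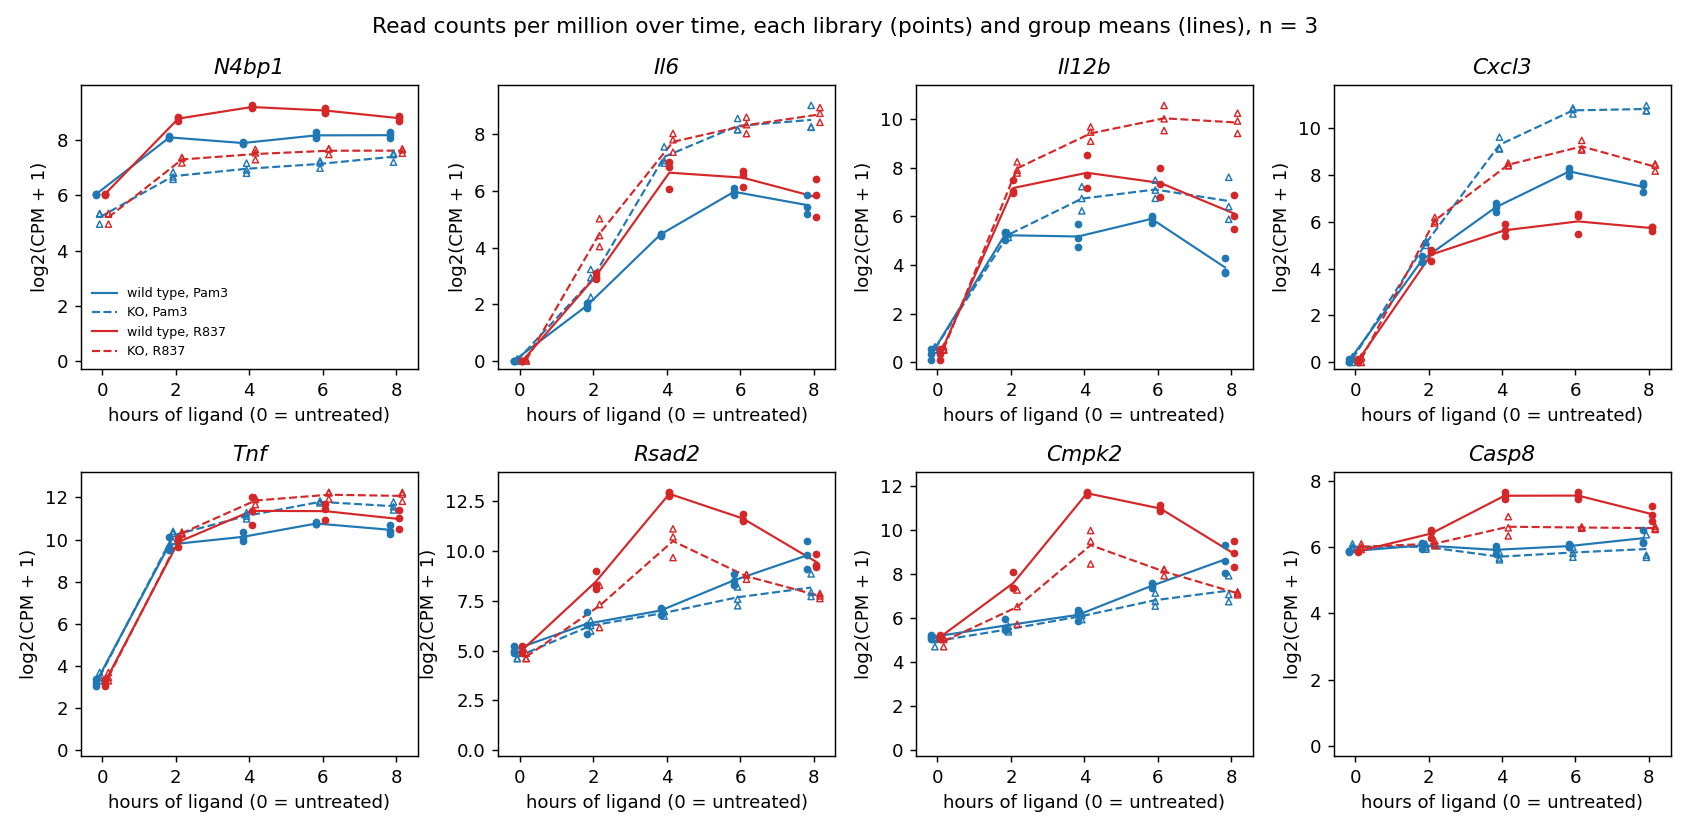
Expression over time of N4bp1, Il6, Il12b, Cxcl3, Tnf, Rsad2, Cmpk2 and Casp8, as log2(CPM + 1) against hours of ligand, with 1 point per library (circles for wild type, triangles for KO). Lines run through the means of n = 3 libraries, solid for wild type, dashed for KO, blue for Pam3 and red for R837. The untreated libraries are drawn for both ligands. Rsad2 in wild-type cells under R837 reached 7548 ± 523 CPM at 4 h while KO cells reached 1577 ± 711 CPM. Cxcl3 in KO cells under Pam3 reached 1783 ± 164 CPM at 8 h against 179.7 ± 24.7 CPM in wild type.

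**Figure D2:**
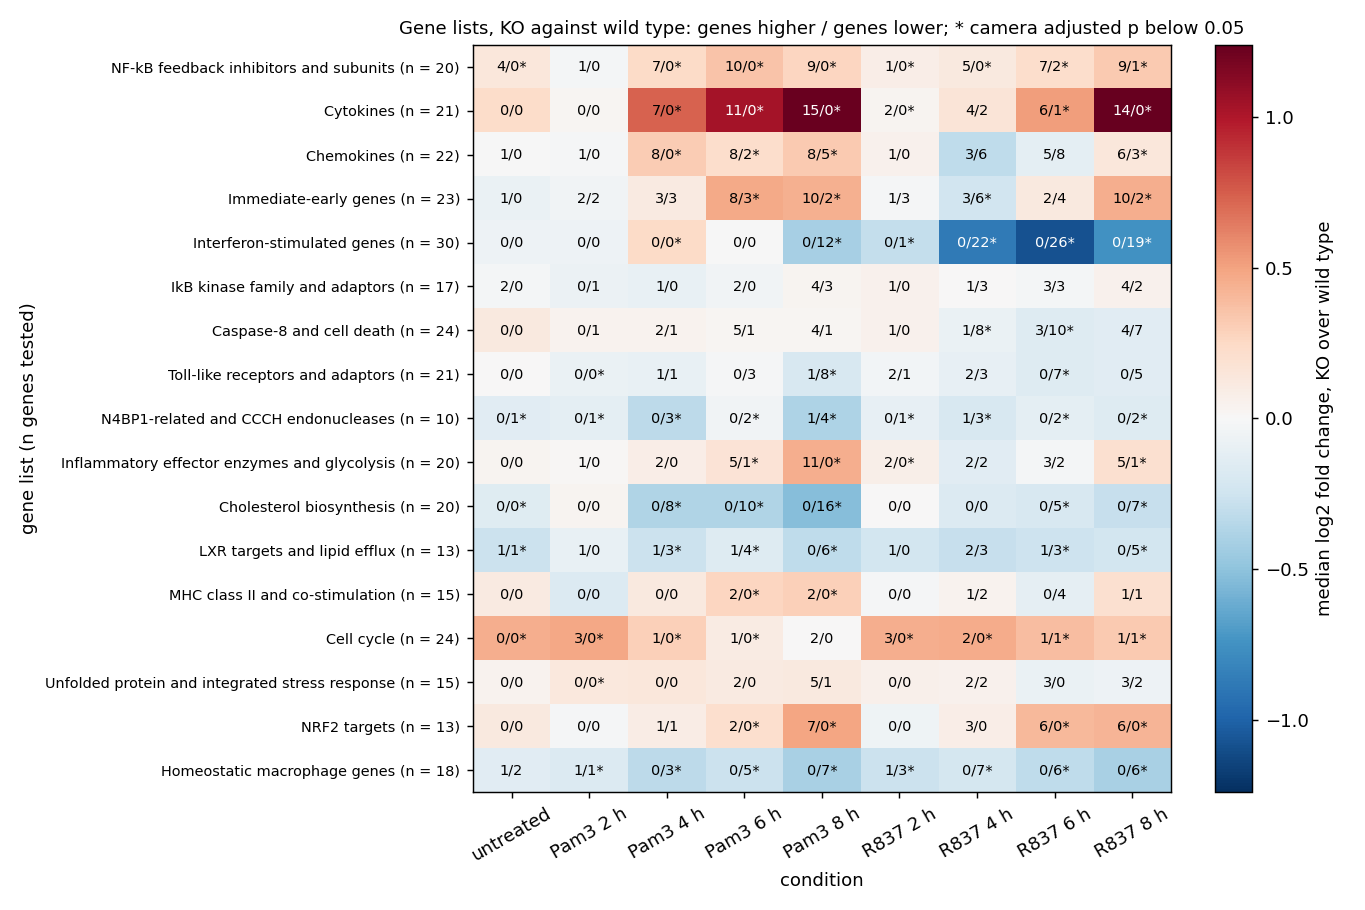
Median log2 ratio of KO to wild type (colour scale) for the 17 function lists (vertical axis, with the number of genes tested) at the 9 conditions (horizontal axis). Each cell gives the numbers of genes higher and lower in KO cells, and an asterisk where the camera adjusted p was below 0.05 with the preset correlation. Over all 26 lists 103 tests between KO and WT passed so, and 30 with an estimated correlation, which the asterisks do not show. The interferon-stimulated list had 22, 26 and 19 genes lower after 4, 6 and 8 h of R837, and the cytokine list 15 and 14 genes higher after 8 h of Pam3 and R837.

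Metabolic lists differed between the genotypes under both ligands. Of 20 cholesterol biosynthesis genes 8 fell and 12 did not pass (12 fell adjusted over the list alone) at 4 h of Pam3, 10 fell and 10 did not pass (13 fell adjusted over the list alone) at 6 h and 16 fell and 4 did not pass at 8 h in KO cells. Dhcr7, the last enzyme of that pathway, was at 9.28 ± 0.981 against 21.9 ± 1.41 CPM at 8 h (log2 -1.23 ± 0.11, edgeR adjusted p = 8.53e-11). The list had camera adjusted p = 1.56e-08, and adjusted p = 0.161 with an estimated correlation at 4 h, adjusted p = 3.85e-09, and adjusted p = 0.143 with an estimated correlation at 6 h and adjusted p = 1.22e-08, and adjusted p = 0.154 with an estimated correlation at 8 h. Under R837 at 8 h 7 fell and 13 did not pass (9 fell adjusted over the list alone) (camera adjusted p = 0.000293, and adjusted p = 0.423 with an estimated correlation). Of 13 targets of the oxysterol receptor LXR 6 fell and 7 did not pass at Pam3 8 h (camera adjusted p = 0.00697). At R837 8 h 5 fell and 8 did not pass (7 fell adjusted over the list alone) (camera adjusted p = 5.65e-05). The lipid droplet gene Plin2 was lower by log2 -1.01 ± 0.09 and -1.01 ± 0.09, and the sterol exporter gene Abcg1 by -0.70 ± 0.14 (edgeR adjusted p from 1.93e-08 to 0.0558 over the alternatives, highest in a fit of the 6 libraries alone) and -1.18 ± 0.14. Of 13 targets of the oxidative stress factor NRF2 7 rose and 6 did not pass (8 rose adjusted over the list alone) at Pam3 8 h, 6 rose and 7 did not pass at R837 6 h and 6 rose and 7 did not pass (9 rose adjusted over the list alone) at R837 8 h. Among these NRF2 targets was the cystine transporter gene Slc7a11 (log2 2.11 ± 0.22, 1.94 ± 0.22 and 2.35 ± 0.23). Their list had camera adjusted p = 7.02e-07 at Pam3 8 h, adjusted p = 1.24e-06 at R837 6 h and adjusted p = 3.67e-06 at R837 8 h. Among 20 effector enzymes 11 rose and 9 did not pass (12 rose and 1 fell adjusted over the list alone) at Pam3 8 h (camera adjusted p = 2.83e-07, and adjusted p = 0.099 with an estimated correlation), with Ptges at log2 1.07 ± 0.13 and the cyclooxygenase gene Ptgs2 at 1.74 ± 0.22. At R837 8 h 5 rose, 1 fell and 14 did not pass (6 rose and 2 fell adjusted over the list alone) of them (camera adjusted p = 0.00194, and adjusted p = 0.366 with an estimated correlation). KO Pam3 8 h replicate 3 belongs to the 8 h Pam3 values, and without it 15 cholesterol genes and 7 LXR targets fell and 8 NRF2 targets and 10 effector genes rose.

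Several markers of resident and core macrophage identity were lower in KO cells under both ligands. Of 18 homeostatic macrophage genes 7 fell and 11 did not pass (9 fell adjusted over the list alone) at Pam3 8 h (camera adjusted p = 0.000852). At R837 8 h 6 fell and 12 did not pass (9 fell adjusted over the list alone) (camera adjusted p = 5.78e-06). The transcription factor gene Maf was lower by log2 -1.27 ± 0.15 at Pam3 8 h. Of 10 core macrophage genes 1 rose, 6 fell and 3 did not pass (1 rose and 8 fell adjusted over the list alone) at Pam3 8 h (camera adjusted p = 0.000598). At R837 6 h 4 fell and 6 did not pass (5 fell adjusted over the list alone) (camera adjusted p = 6.58e-05). Fcgr1, the high-affinity receptor gene for immunoglobulin G, was at 397 ± 30.3 against 1714 ± 195 CPM at R837 6 h (log2 -2.11 ± 0.17) and lower by log2 -1.74 ± 0.16 at Pam3 8 h. Without KO Pam3 8 h replicate 3, 5 homeostatic genes fell at Pam3 8 h, and 1 core macrophage gene rose and 4 fell. Of the 10 stromal and endothelial markers 4 fell and 6 did not pass (5 fell adjusted over the list alone) at Pam3 2 h (camera adjusted p = 3.09e-07). At R837 2 h 3 fell and 7 did not pass (4 fell adjusted over the list alone) (camera adjusted p = 9.73e-06). Col1a2 stood at log2 -1.35 ± 0.20 and -1.22 ± 0.20. Of 11 neutrophil markers 5 fell and 6 did not pass at R837 6 h (camera adjusted p = 0.00085, and adjusted p = 0.187 with an estimated correlation). The collagenase gene Mmp8 stood at log2 -1.45 ± 0.21 and the lactoferrin gene Ltf at -1.51 ± 0.28. The lowest camera adjusted p of the 9 comparisons was 0.441 for monocyte markers, 0.568 for B cell markers, 0.503 for mast cell and basophil markers and 0.108 for osteoclast markers. For dendritic cell markers it was 0.00648, and for megakaryocyte markers 0.045, both at Pam3 2 h, where adjusted p = 0.187 and 0.376 with an estimated correlation.

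**Figure D3:**
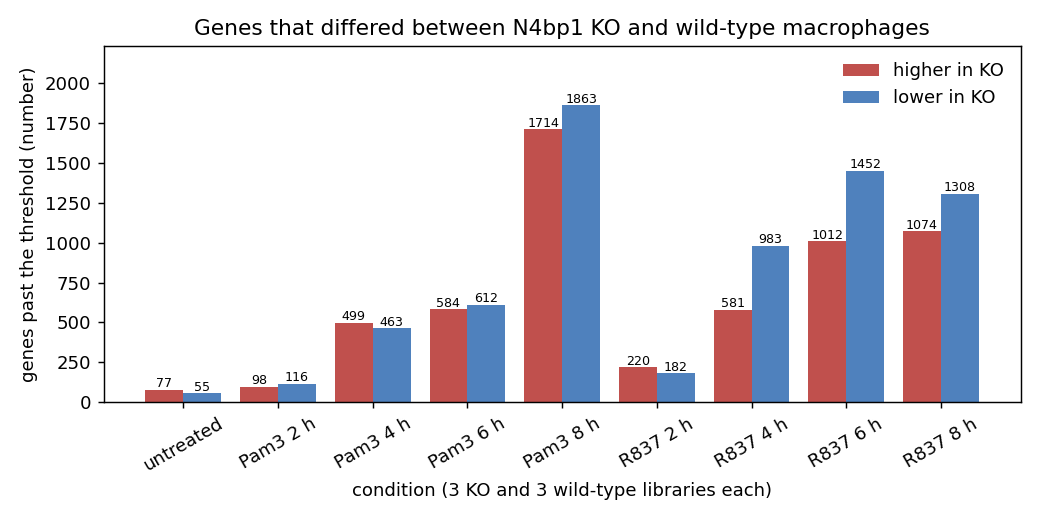
Number of genes (vertical axis) that passed the edgeR test between KO and wild-type macrophages at each of the 9 conditions (horizontal axis, 3 libraries of each genotype). Red bars are genes higher and blue bars genes lower in KO cells, without error bars. The bars run from 77 higher and 55 lower in untreated cells to 1714 and 1863 at 8 h of Pam3.

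Whether the response itself differed between genotypes was tested with interaction terms. For Pam3 against untreated cells, 694 genes passed an F-test over the 4 times, for R837 1119, and for R837 against Pam3 617. The tests against untreated cells can also pass through changes of the genotype difference between the treated times. By single times 6, 58, 165 and 669 genes passed for Pam3 at 2, 4, 6 and 8 h, 14, 470, 977 and 490 for R837, and 1, 174, 395 and 30 for the difference between ligands. Casp8 rose less under R837 in KO than in WT cells, with interaction log2 terms of -1.06 at 4 h and -1.11 at 6 h (edgeR F-test adjusted p = 4.28e-05). For Pam3 its adjusted p was 0.479 (0.0366 without KO Pam3 8 h replicate 1, and from 0.0366 to 0.691 over the alternatives). Between ligands its genotype difference changed by log2 -0.71 at 4 h and -0.78 at 6 h (edgeR F-test adjusted p = 0.00137). Cmpk2 differed for R837 (edgeR F-test adjusted p = 0.000487) and between ligands (adjusted p = 0.00023), and Rsad2 likewise (adjusted p = 0.00573 and 0.00276). Cxcl3 differed for both Pam3 and R837 (edgeR F-test adjusted p = 8.13e-08 and 0.000109), as did Il12b (adjusted p = 0.00762 and 0.00159) and Tnfaip3 (adjusted p = 3.33e-05 and 0.00281). For Pam3 the log2 terms of Cxcl3 at 2, 4, 6 and 8 h were -0.58, 1.37, 1.285 and 1.99. For Il12b they were -0.81, 0.76, 0.42 and 2.15. For R837 those of Cxcl3 were 0.17, 1.49, 1.86 and 1.32, and those of Il12b -0.02, 0.71, 1.82 and 2.86. At single times neither Cxcl3 nor Il12b passed, with lowest edgeR adjusted p = 0.465 for Pam3 and 0.562 for R837 for Cxcl3, and 0.335 and 0.272 for Il12b. Their F-tests thus do not show a change from untreated cells at any given time. With limma voom in place of edgeR the F-test adjusted p was 0.806 and 0.982 for Cxcl3 and 0.923 and 0.959 for Il12b. These were the highest of the alternatives, which ran down to 5.43e-60 and 1.32e-25 for Cxcl3 and to 6.8e-71 and 1.26e-85 for Il12b. Il6 lay near the threshold, with edgeR F-test adjusted p = 0.0644 for Pam3 and 0.0276 for R837. Its interaction log2 terms at 2, 4, 6 and 8 h were -1.40, 0.28, -0.19 and 0.52 for Pam3. For R837 they were -0.86, -1.47, -0.68 and 0.32. Several of these terms were negative, so the F-test does not show a stronger rise in KO cells. Untreated WT libraries held no Il6 counts, which leaves the size of each term poorly determined. For Pam3 Il6 passed with DESeq2 (adjusted p = 0.0041), with the replicate number as a block (0.00253), with no filter or the stricter filter (2.08e-22 and 0.0499) and on the compared groups alone (0.0137). It also passed without KO 2 h replicate 1, WT 8 h replicate 2 or KO 8 h replicate 2 (adjusted p = 0.0394, 0.0497 and 0.0465). The block by number does not follow the Y-linked level of WT libraries from untreated to Pam3, so its value for Pam3 carries little weight. For R837 Il6 no longer passed on the compared groups alone (adjusted p = 0.0812) or with limma voom. The same held without WT 4 h replicate 2 or 3, KO 4 h replicate 2, WT 8 h replicate 1 or 2, or KO 8 h replicate 1 or 3 (adjusted p = 0.0602, 0.0747, 0.0724, 0.102, 0.0719, 0.0865 and 0.0565). Over the alternatives its adjusted p ran from 2.08e-22 to 0.971 for Pam3 and from 1.32e-25 to 1 for R837. Tnf did not pass for either ligand (edgeR F-test adjusted p = 0.243 and 0.423), but had adjusted p = 9.75e-09 and 3.22e-06 with no filter on low counts. The fit with no filter tested 27757 genes in place of 14970. For Il6 and Tnf its p-values lay far below those of the main fit, for a reason that was not tested. They therefore carry little weight. Fitted on the compared groups alone Tnf had adjusted p = 0.0376 for Pam3, and over the alternatives from 9.75e-09 to 0.485 for Pam3 and from 3.22e-06 to 0.788 for R837. Neither did Ikbke pass (adjusted p = 0.248 and 0.211) or Tbk1 (adjusted p = 0.807 and 0.142). For R837 Tbk1 had adjusted p = 0.0261 without KO 4 h replicate 3 and 0.0191 without WT 8 h replicate 3 (from 0.0191 to 0.65 over the alternatives). The Pam3 count of 694 became 1185 and 1064 without KO Pam3 8 h replicates 1 and 2, and the count of 617 between ligands became 962 without KO Pam3 8 h replicate 1.

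The genotype differences under the 2 ligands overlapped in genes at each time. At 2 h 57 genes were higher and 66 lower in KO cells under both ligands. At 4 h the shared counts were 233 higher and 208 lower, and at 6 h they were 295 and 360. At 8 h 631 genes were higher and 802 lower under both ligands. The Pam3 and R837 comparisons share no libraries at a given time, but WT libraries of equal Y-linked level had deviations that correlated between the ligands (0.262 to 0.692). The 2 comparisons are therefore not independent, and the overlap that independent lists would give is no measure of chance here. Il6, Il12b, Cxcl3 and Ptx3 were among the genes higher under both ligands at 8 h, and Fcgr1 and Plin2 among those lower.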

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

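The tests of interaction in this part were planned and none was chosen after its result was seen. Each result here stands out because the difference between KO and WT differed between treatments in an F-test over 4 times (edgeR, Benjamini-Hochberg adjustment). That difference was not the same in untreated cells and at the 4 times of Pam3 in 694 genes, and of R837 in 1119. Between R837 and Pam3 it differed in 617. The tests against untreated cells can also pass through changes between the treated times. The Pam3 count was 1185 without KO Pam3 8 h replicate 1 and 1064 without replicate 2, and the count between ligands was 962 without KO Pam3 8 h replicate 1. The real split of the libraries gave these counts and no other split called more than 1 gene. With 10 splits a share under 0.05 cannot be reached. Each other split mixes KO and WT libraries in both groups, which adds real differences to the spread, so its low count is no measure of chance.

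For Pam3 the smallest adjusted p was that of Ptger4, a prostaglandin receptor gene (3.21e-09), whose interaction term reached log2 -2.22 at 8 h. The complement receptor gene C3ar1 (1.03e-08) had a term of -1.34 and the eotaxin receptor gene Ccr3 (1.43e-08) one of -1.20 at 8 h. Ier3 (1.65e-08), an immediate-early gene, and the sialyltransferase gene St3gal3 (2.35e-08) had terms of 1.39 and 1.34 at 8 h.

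For R837 the smallest adjusted p was shared by Osbpl3, an oxysterol-binding protein gene with a term of log2 1.33 at 6 h, and Ehd4, an endocytosis gene with a term of -1.57 at 6 h (both 5.9e-09). Zc3h12d, a CCCH zinc-finger gene, had a term of -1.64 at 8 h, Inppl1, a lipid phosphatase gene, one of -1.01 at 8 h, and St3gal3 one of 1.47 at 6 h (all 1.26e-08).

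Between R837 and Pam3 the smallest adjusted p was that of the aldehyde dehydrogenase gene Aldh1b1 (3.56e-09), with a term of log2 -2.29 at 4 h. The haem oxygenase gene Hmox2 (1.4e-07), Carhsp1 (2.29e-07) and Ube2l6 (3.34e-07), which encodes the enzyme that conjugates ISG15, had terms of -0.97, -1.17 and -1.09 at 6 h. Nub1 (4.71e-07), an interferon-inducible regulator of NEDD8, had a term of -0.81 at 4 h.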

How the results depend on the processing

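The fits without KO Pam3 8 h replicate 3, with the Y-linked level as a covariate and with WT cultures blocked by Y-linked level were tests chosen only after the data were seen. Counts of genes stayed within 1.5 times the reported ones with RLE size factors, with the stricter filter, with the replicate number as a block and with WT cultures blocked by Y-linked level. Other alternatives moved some counts further, and the cause was not tested unless named. Without a filter on low counts 368 genes passed in untreated cells, 501 at 2 h of Pam3, 636 at 2 h of R837, 1452 for the Pam3 interaction and 1207 for the interaction between ligands. DESeq2 called 242, 386, 610, 1160 and 945 in the same order, and limma voom called 1164 for the Pam3 interaction. With the Y-linked level as a covariate the counts were 275 in untreated cells, 399 at 2 h of Pam3 and 636 at 2 h of R837. Without KO Pam3 8 h replicate 3 there were 324 at 2 h of Pam3. Fits of only the groups compared, with fewer libraries and a different set of genes tested, called 330, 506 and 451 at 2, 6 and 8 h of Pam3 and 713 at 2 h of R837. With an estimated correlation 30 list tests passed between KO and WT, in place of 103, and 65 in place of 105 in wild-type responses. With each library left out in turn, which leaves fewer samples, counts between KO and WT ran from 40 to 93 in untreated cells, from 63 to 230, 409 to 1192 and 635 to 1474 at 2, 4 and 6 h of Pam3, and from 197 to 266 and 932 to 1469 at 2 and 4 h of R837. They ran from 353 to 792 and 975 to 1901 for R837 against Pam3 at 2 and 8 h, from 505 to 1185 for the Pam3 interaction, and from 492 to 962 for that between ligands. For the other comparisons and the R837 interaction they stayed within 1.5 times the reported count. Whether more genes were higher or lower turned with at least 1 alternative or left-out library in each comparison other than KO against WT at 4, 6 and 8 h of R837 and R837 against Pam3 at 6 and 8 h, so no balance is claimed for the rest.

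The replicate numbers did not pair KO with WT libraries, since equal numbers had the highest correlation for 0 to 2 of 3 libraries, with correlations from -0.279 to 0.212. With the replicate block 168 genes passed in untreated cells and 2536 at 6 h of R837. In the wild-type responses to R837, where the numbers pair, the block changed no call of a gene or list test printed here. With WT cultures blocked by Y-linked level 471 of 475 wild-type results of the genes named here kept their direction and side of the threshold, and 3 gained a call, all in R837 against Pam3 and none of them printed here. Over the genes named here, 982 of 986 gene results kept their direction and side of the threshold with RLE size factors, 883 of 986 without a filter, 963 of 965 with the stricter filter, 949 of 977 with DESeq2 and 876 of 967 with only the groups compared. With limma voom 944 of 986 did and 17 lost a call. With the Y-linked level as a covariate 491 of 511 did and 6 lost a call. With single libraries left out 7425 of 7878 did, 339 lost and 36 gained a call, and no called gene reversed direction. Depth limits what can be tested, as library totals went down to 20.03 M counts and 14970 of 27757 genes with any count passed the filter.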

Other observations

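The tests of a library of low complexity, of sex, of neighbours on chromosome 8 and of depth, and the fits without KO Pam3 8 h replicate 3 and with the Y-linked level, were tests chosen only after the counts of genes they bear on were seen. Further lists fixed in advance held genes that passed the test between genotypes, while most of their list tests did not pass with an estimated correlation. Of 23 immediate-early genes 10 rose, 2 fell and 11 did not pass (10 rose and 3 fell adjusted over the list alone) at 8 h of Pam3 (camera adjusted p = 0.00619, and adjusted p = 0.223 with an estimated correlation). At 8 h of R837 10 rose, 2 fell and 11 did not pass (13 rose and 4 fell adjusted over the list alone) (camera adjusted p = 0.00258, and adjusted p = 0.168 with an estimated correlation). Ier3 stood at log2 1.13 ± 0.12 under Pam3 and Maff at 1.26 ± 0.18 under R837. Without KO Pam3 8 h replicate 3, 8 immediate-early genes rose and 2 fell at 8 h of Pam3. After 4 h of R837 3 rose, 6 fell and 14 did not pass (4 rose and 8 fell adjusted over the list alone) (camera adjusted p = 0.0122, and adjusted p = 0.287 with an estimated correlation), with Atf3 and Jun at log2 -1.28 ± 0.13 and -1.30 ± 0.14. Of 21 Toll-like receptor and adaptor genes 7 fell and 14 did not pass (9 fell adjusted over the list alone) after 6 h of R837 (camera adjusted p = 0.0125, and adjusted p = 0.464 with an estimated correlation), among them Tlr3 and Tlr9 at log2 -2.10 ± 0.25 and -1.37 ± 0.24.

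Of 24 cell cycle genes 3 rose and 21 did not pass (11 rose adjusted over the list alone) after 2 h of Pam3 (camera adjusted p = 1.11e-13, and adjusted p = 0.0904 with an estimated correlation). They were the replication helicase genes Mcm5, Mcm4 and Mcm3 at log2 0.71 ± 0.16, 0.54 ± 0.13 and 0.53 ± 0.14. The calls of Mcm5, Mcm4 and Mcm3 ended without KO Pam3 2 h replicate 2 (adjusted p = 0.123, 0.18 and 0.249), without KO replicate 3 (0.0692, 0.107 and 0.16) and without WT replicate 3 (0.0739, 0.146 and 0.215), and those of Mcm5 and Mcm3 also without WT replicate 2 (0.0838 and 0.128). Over all alternatives their adjusted p ran from 2.86e-06 to 0.123, from 0.00383 to 0.18 and from 0.00192 to 0.249. Of 15 MHC class II and co-stimulation genes 2 rose and 13 did not pass at 8 h of Pam3 (camera adjusted p = 0.00933, and adjusted p = 0.508 with an estimated correlation), with Cd40 at log2 1.43 ± 0.18. Of 15 genes of the unfolded protein and integrated stress response 5 rose, 1 fell and 9 did not pass (6 rose and 3 fell adjusted over the list alone) at 8 h of Pam3 (camera adjusted p = 0.067). Of 10 N4BP1-related and CCCH endonuclease genes, N4bp1 itself among them, 3 fell and 7 did not pass (4 fell adjusted over the list alone) after 4 h of Pam3 (camera adjusted p = 5.71e-05), with Zc3h12d at log2 -0.83 ± 0.13. N4bp1 is the gene knocked out, so its fall was fixed by the design. The list was not tested without it, so the camera value does not speak for the related genes alone.

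The number of genes that differed between KO and WT rose from 1196 at 6 h of Pam3 to 3577 at 8 h, a ratio of 2.99, but in fits of only the 6 libraries compared it was 506 at 6 h and 451 at 8 h, fits that also test a different set of genes, and the cause of that loss was not tested. Technical weight on 1 library of low complexity, KO Pam3 8 h replicate 3, is a candidate explanation. Without that library the counts were 1580 and 2680, a ratio of 1.7, and 2133 of the 3577 genes still passed, but with 2 KO libraries at both times the ratio ran from 1.35 to 3.2 depending on which were kept. The part of this library in the higher count cannot be told apart from the loss of a replicate, since 3 libraries a group leave too few to compare. Spread in the KO Pam3 8 h group was not limited to replicate 3. The chi-square statistic per degree of freedom was 85.25 between replicates 1 and 2, 46.19 between 1 and 3, and 89.8 between 2 and 3. In the KO Pam3 6 h group replicate 3 also stood apart. There the statistic was 16.72 between replicates 1 and 2, 78.45 between 1 and 3, and 68.57 between 2 and 3. At 8 h 4752 genes passed without KO replicate 1 and 4045 without KO replicate 2. A longer exposure to the ligand, which the design names, stays open as an untested explanation.

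KO and WT cells differed in 132 genes before treatment, and KO libraries held at most 0.208 CPM of Y-linked transcripts while WT libraries reached 206.7 CPM. With the Y-linked level as a covariate 275 genes were called, 2.08 times as many. The ratio was 1.13 to 3.44 with each of the 6 libraries left out of both fits. A linear term for the Y-linked level thus did not remove the calls. KO libraries hardly vary in that level, so the term rests on WT cultures alone. Other differences between those cultures can enter the term and shrink the spread, so the fit cannot decide whether sex is the cause. Genes within 10 Mb of N4bp1 on chromosome 8 made up 1 of the 132 calls, or 0.758% (exact Clopper-Pearson 95% interval 0.0192 to 4.15), against 1.12% of the genes tested. This argues against passenger variants acting on neighbouring genes as the source of most of the calls. It cannot exclude an effect on a few neighbours. Only 1 WT culture lacks Y-linked counts, passenger variants acting on distant genes and differences between animals other than sex were not tested, and the genotype, which the design names, stays a hypothesis.

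After 6 h of R837 KO and WT cells differed in 2464 genes. With the Y-linked level as a covariate 2782 were called, 1.13 times as many. The ratio was 1.07 to 1.22 with each of the 6 libraries left out of both fits. Here too the term rests on WT cultures alone and can take up their other differences, so the fit cannot decide whether sex is the cause. KO libraries held 30.4 to 45.9 M counts and WT libraries 31.0 to 37.2 M. With all 6 libraries thinned to 30.4 M counts, 95.3% of the calls were left as the median of 3 draws (94.9 to 95.5%), with 2411 to 2433 genes called, which argues against depth. The genotype, which the design names, stays a hypothesis, and differences between animals other than genotype stay open here as well.

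In comparisons of 3 libraries against 3 there are 10 splits, so a share under 0.05 cannot be reached. In each of the 24 comparisons and tests of interaction the real split was the only 1 of the 10 to reach its number of genes. Between KO and WT, fitted with all 54 libraries, it called 132 genes in untreated cells, 214, 962, 1196 and 3577 after 2, 4, 6 and 8 h of Pam3, and 402, 1564, 2464 and 2382 after 2, 4, 6 and 8 h of R837. Fitted with the 6 libraries compared, it called 7231, 8289, 8861 and 8445 genes in the wild-type response to Pam3 at 2, 4, 6 and 8 h, 7572, 9008, 9517 and 8971 in that to R837, and 834, 3835, 4238 and 1250 for R837 against Pam3. The highest other split called 316 genes between KO and WT at 8 h of Pam3 and at most 1 gene in each of the others. Every other split mixes the 2 real groups, which adds real differences to the spread, so these low counts are no measure of chance.

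Levels of Y-linked transcripts set 3 kinds of WT library apart, and their order among the replicate numbers differed between conditions. Untreated libraries and those of R837 had high, middle and no Y-linked counts in replicates 1, 2 and 3. For Pam3 at 2 h replicates 1, 2 and 3 were middle, high and none, and at 4, 6 and 8 h none, high and middle. Libraries of equal Y-linked level had correlated deviations from their group means in every wild-type comparison, with a lowest correlation of 0.219. The sum of immunoglobulin transcripts was 20.4 to 158.6 CPM in WT libraries and 132.5 to 301.5 CPM in KO libraries.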
